A study of Mus musculus with 12 samples.

How the data were processed

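RNA was measured in Vg4+Vd4+ gamma delta T cells of C57BL/6 mice, in 4 groups of 3 libraries given by genotype (wild type or NF-kB1 deficient) and by the cream put on the skin (sham or imiquimod). RNA was extracted with Trizol and made into libraries with the QuantSeq 3' FWD kit, per the labels' protocols. That kit reads a single fragment near the 3' end of each polyadenylated transcript, so read numbers do not scale with transcript length. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation and the normalization tool are not given in the sources used here.

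The deposited table held 45796 genes by 12 libraries, and the values are log2 normalized read counts as the authors deposited them. Of these genes 9732 were above 0 in any library and 495 in all of them. Each value was taken back to the linear scale, called the normalized value from here on. No linear value lay between 0 and 1, and a gene at 0 is described only as listed at 0. In wild-type sham replicate 2, NF-kB1-deficient sham replicate 1 and the 3 NF-kB1-deficient imiquimod libraries, where 1 read was worth 0.488 to 0.735, 0 genes stood at 1 read, and in wild-type sham replicate 2 also 0 at 2 reads. A listed 0 can therefore hide 1 read in these 5 libraries, or 2 reads in that replicate, and numbers of genes above 0 leave such genes out. Gapdh, which every cell uses, was also at 0 in 5 libraries, while the actin gene Actb stood between 97.0 and 213 in all 12. Columns were matched to samples by their titles, and no column was left unused. No 2 libraries held identical values (0 of 66 pairs). The table holds 26 symbols that a spreadsheet turned into dates, and 12 symbols on more than 1 line.

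Low values fell on steps, from which the value of 1 read was estimated for each library at 0.488 to 1.98. Under 20 reads, 71.2% to 80.2% of values lay within 0.01 read of a whole number, too few to recover the reads, so no count test was run. The steps imply 20507 to 69454 reads on genes per library, with a median of 35383. These depths come from the values and are estimates. The libraries carry no molecular identifiers in the table, so reads that are copies of 1 molecule cannot be removed.

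Tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8). The values tested were log2(normalized value + 1). Genes with a mean normalized value of at least 5 over the 12 libraries were kept, which left 1571. A fold change on this scale understates the change of genes with low values. All 12 libraries entered 1 fit with 1 coefficient per group, followed by eBayes with trend and robust set (8 residual degrees of freedom, median prior degrees of freedom 145). The moderated tests therefore lean strongly on the spread shared by genes of like mean. The Benjamini-Hochberg adjustment ran over the 1571 genes in each comparison, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error. Comparisons were imiquimod against sham within each genotype, NF-kB1 deficient against wild type within each treatment, and the difference between both treatment responses (the interaction). Nothing in the labels says that the 3 replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

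Gene lists, comparisons, filters and the rule for naming genes were chosen before the data were examined. There were 34 lists, of which 768 of 769 members had a line in the table. The 18 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with the adjustment over those 18. Each was also tested with an estimated correlation and with fry, a rotation test of whether a list's genes move one way on balance. Lists share some members, such as Junb, Il7r, Il2rb and H2afz. Lists with too few tested members were not tested; their summed normalized value per library is given instead, or, for markers of other cells, the highest shares of the library's summed value.

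Genes are named by a rule. For each comparison it takes the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, with a mean of at least 5 once each library total is scaled to 1000000 (for the interaction without the overlap condition). It adds up to 4 called members of each list by adjusted p, and always 14 genes of NF-kB and of cytokine production. In a direction with fewer than 5 calls it adds the 5 genes with the lowest unadjusted p. A gene named for one comparison may be named for another. Some genes that the rule takes are not reported here.

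The test was run on simulated data with the mean of each gene over the 12 libraries, the estimated depths and a common dispersion of 0.292. Known folds were planted in the wild-type imiquimod libraries, and 1599 genes were tested. The test called 1 of 44 genes changed 2-fold, 19 of 46 changed 4-fold (41.3%), 35 of 43 changed 8-fold and 36 of 45 changed 16-fold. There were 4 false calls, and 0 in a simulated comparison without change. The simulation was not matched to the zeros beside high values in the real data, so real recovery may be lower.

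Alternatives were another pseudocount (0.1 or 10), no filter or a mean of at least 20, limma without trend or robust, a fit of the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were equal totals without the 10 most abundant genes, recomputed median-of-ratios factors, a common floor of 1.98, library weights, the deposited log2 values as they are, and reads thinned to equal depth. For the last, values were divided by the value of 1 read, rounded to whole reads, drawn down to the total of the shallowest library in 20 draws and tested gene by gene, so it shares the uncertainty of the implied reads. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 denotes, and 106 of 112 genes looked up by symbol were found. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.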

Results

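The libraries measured gene expression in gamma delta T cells that carry the Vg4 and Vd4 receptor chains, a T cell subset known for rapid cytokine production in the skin. The cells came from lymph nodes draining the skin of C57BL/6 mice. There were 3 libraries in each of 4 groups: wild-type mice with sham cream, NF-kB1-deficient mice with sham cream, wild-type mice with imiquimod cream and NF-kB1-deficient mice with imiquimod cream. Imiquimod is a Toll-like receptor agonist whose repeated use on mouse skin gives a psoriasis-like inflammation. NF-kB1 (p105, processed to p50) is a subunit of the NF-kB transcription factors. Summed normalized values per library ran from 31878 (NF-kB1-deficient sham replicate 2) to 40618 (wild-type imiquimod replicate 3).

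Depth was low. The steps of the values imply 30540, 69454 and 27960 reads on genes in the wild-type sham libraries and 47412, 29115 and 27121 in the NF-kB1-deficient sham libraries. They imply 35155, 35611 and 20507 reads in the wild-type imiquimod libraries and 67043, 45957 and 51153 in the NF-kB1-deficient imiquimod libraries. The number of genes above 0 ran from 2724 in wild-type imiquimod replicate 3 to 5182 in NF-kB1-deficient imiquimod replicate 1. These numbers leave out genes at 1 read in the 5 libraries where 1 read was worth less than 1, since the table holds no value between 0 and 1. Over the 1571 genes tested, the median SE of a log2 fold change was 1.12, and the median 95% interval reached 2.21 to either side. Smaller changes were therefore resolved mainly for abundant genes. On the first principal component of the tested genes (21.3% of the variance), the wild-type imiquimod libraries lay at 34.6, 20.4 and 59.4, and the other 9 libraries lay below 0. Markers of other cell types took at most 0.159% of a library's summed value for any list fixed beforehand, the highest share being that of macrophages, monocytes and dendritic cells in NF-kB1-deficient sham replicate 1. Tcrb, the T cell receptor beta chain locus, is in none of those lists. It was at 103 in wild-type sham replicate 1, where the alpha beta T cell list summed to 0.

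Nfkb1 (Entrez 18033; GRCm38 chromosome 3, 135584655 to 135691547, minus strand, protein coding), the gene named by the genotype, was low in every group. Its normalized values were 6.71, 4.38 and 1.24 in the wild-type sham libraries and 8.82, 1.09 and 2.52 in the NF-kB1-deficient sham libraries. Under imiquimod they were 7.34, 21.0 and 0 in the wild-type and 5.41, 6.64 and 5.84 in the NF-kB1-deficient libraries. The genotypes did not differ by test, with a log2 fold change of -0.12 ± 1.19 (SE) in sham (adjusted p = 0.997) and 0.29 ± 1.19 in imiquimod (adjusted p = 0.940). Without wild-type imiquimod replicate 3 the latter was -0.96, and without 1 library the sham fold ran from -0.74 to 0.38, so neither has a stable sign. The labels do not say which part of the gene is changed, and a 3' tag can lie outside it, so these values check nothing about the genotype labels. The other NF-kB subunits Nfkb2, Rel, Rela and Relb stayed under the filter and were not tested.

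The first comparison asked what imiquimod changes in these cells in wild-type mice. Transcripts of a tubulin and of nucleolar proteins rose. Tuba1b, an alpha tubulin (Entrez 22143; chromosome 15, 98931425 to 98934565), went from 9.59 ± 1.55 in sham to 139 ± 64.3 in imiquimod (mean ± SD, n = 3 each), a log2 fold change of 3.61 ± 0.53 (SE; limma adjusted p = 1.73e-07). The nucleolar proteins Ncl (nucleolin; Entrez 17975; chromosome 1, 86344719 to 86359400) and Npm1 (nucleophosmin; Entrez 18148; chromosome 11, 33152287 to 33163206) rose by 1.96 ± 0.36 (adjusted p = 0.000101) and 2.73 ± 0.52 (adjusted p = 0.000143) on the log2 scale. Ncl went from 39.4 ± 0.296 to 164 ± 57.6. Malat1, an abundant nuclear non-coding RNA (Entrez 72289; chromosome 19, 5795690 to 5802672), fell from 1240 ± 179 to 325 ± 83.0, with a log2 fold change of -1.96 ± 0.18 (adjusted p = 2.59e-18). Tuba1b, Malat1, Btg1, Hsp90ab1, Serbp1 and Arl4c are named for this comparison because other comparisons name them.

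Among the single genes that fell were H2-K1, Cd27, Btg1, Lck and Utrn. H2-K1, a classical MHC class I heavy chain (Entrez 14972; chromosome 17, 33996017 to 34000347), fell from 134 ± 22.2 to 55.4 ± 22.8 (log2 fold change -1.32 ± 0.31, adjusted p = 0.00338). The costimulatory receptor gene Cd27 (Entrez 21940; chromosome 6, 125232622 to 125237010) fell from 43.7 ± 17.9 to 4.82 ± 1.30 (-2.89 ± 0.66, adjusted p = 0.00274), and the antiproliferative gene Btg1 (Entrez 12226; chromosome 10, 96617006 to 96622809) from 47.9 ± 14.5 to 6.01 ± 1.33 (-2.78 ± 0.60, adjusted p = 0.00108). Lck, the kinase that starts T cell receptor signalling (Entrez 16818; chromosome 4, 129548344 to 129573641), was at 36.5, 37.6 and 30.4 in sham and at 1.05, 0 and 6.93 in imiquimod (-3.82 ± 0.76, adjusted p = 0.000290). Utrn, which encodes utrophin, was at 30.7, 32.9 and 41.0 in sham and at 5.24, 0 and 0 in imiquimod (-4.27 ± 0.90, adjusted p = 0.000797). Both stayed called in every alternative setting, but with zeros their folds are loosely fixed. Over those settings the log2 fold change ran from -5.22 to -1.86 for Lck and from -6.53 to -1.96 for Utrn.

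**Figure D1:**
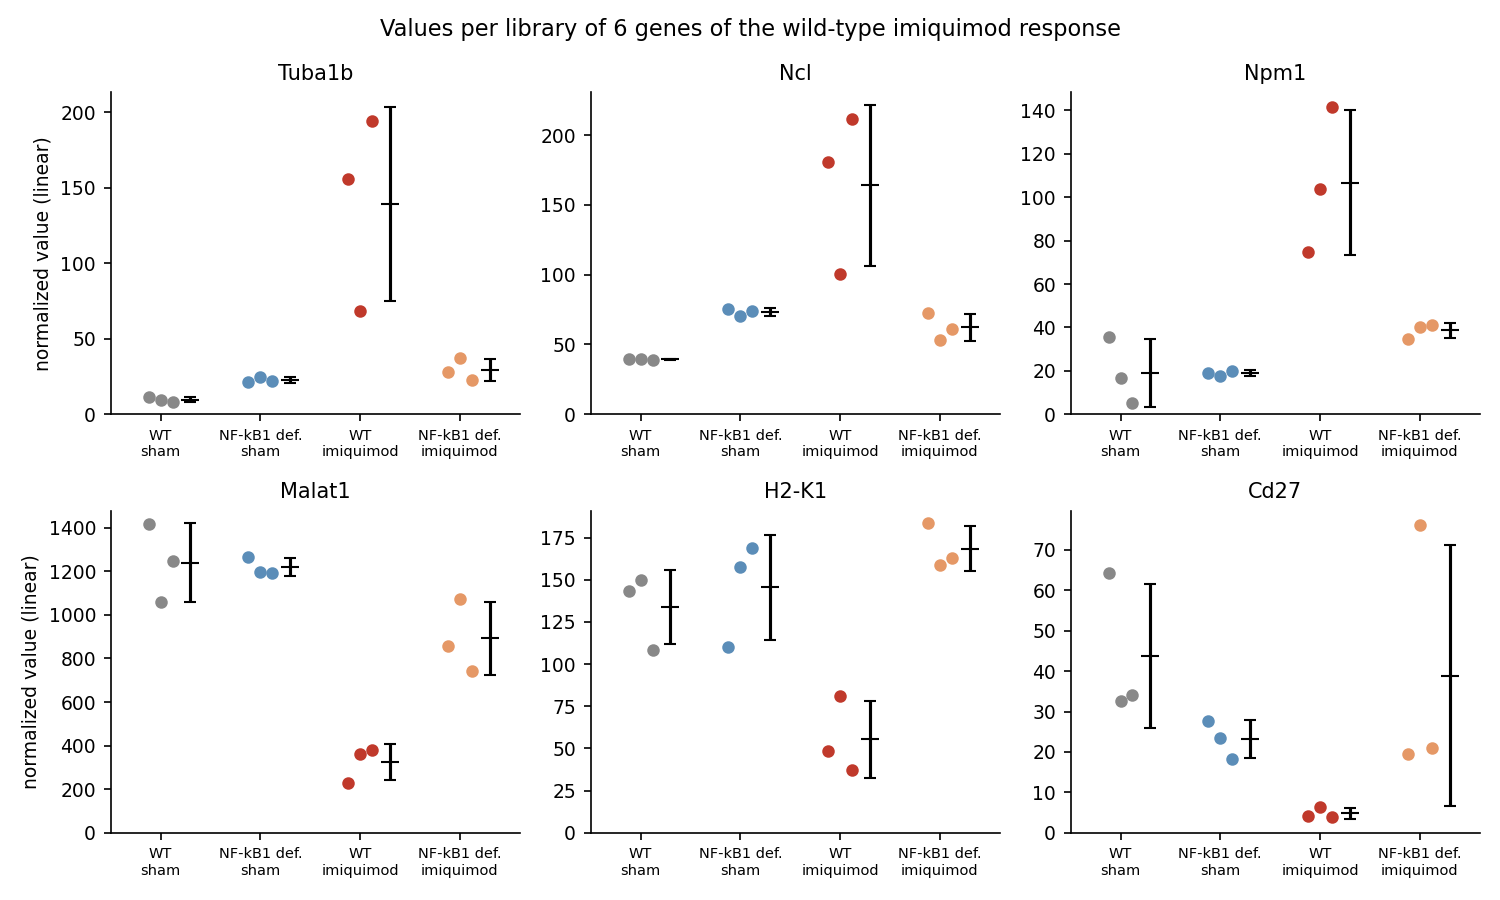
Normalized value (linear scale) of Tuba1b, Ncl, Npm1, Malat1, H2-K1 and Cd27 in each of the 4 groups; each point is 1 library and the bar with its line is the mean ± SD of 3 libraries. The wild-type imiquimod group stands apart in each panel, at 139 ± 64.3 for Tuba1b and 325 ± 83.0 for Malat1, while NF-kB1-deficient imiquimod libraries average 29.2 and 892.

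In total 51 of 1571 genes were called in wild-type cells, 26 higher and 25 lower, and 313 had an unadjusted p under 0.05. With equal totals the split was 18 higher and 32 lower, and with a pseudocount of 10 it was 47 and 25. The 2 groups did not overlap in 49 of the 51 called genes and in 21.5% of all tested genes. Chance gives at most 10% for a gene, and less where values tie at 0. Genes are not independent, so such a share has no known spread. The count was 26 without wild-type sham replicate 3, 28 without wild-type imiquimod replicate 1, 28 in a fit of the 6 libraries alone, 26 with a pseudocount of 0.1, 18 without trend or robust and 11 with no filter. Of 34 called genes followed through these settings, 11 stayed called whichever library was left out: Tuba1b, Ncl, Npm1, Hsp90ab1, Calr, Malat1, H2-K1, Cd27, Btg1, Lck and Utrn. The other 23 were not called without at least 1 library, with highest adjusted p between 0.0567 (Ms4a6b, without wild-type imiquimod replicate 1) and 0.269 (Ifi203, without wild-type sham replicate 3). Without trend and robust, Malat1 (adjusted p = 0.140), Ncl (0.140), Npm1 (0.0883), H2-K1 (0.288), Cd27 (0.0596), Btg1 (0.0519) and Hsp90ab1 (0.240) were not called, and with no filter neither were H2-K1 (0.202), Cd27 (0.0654) and Btg1 (0.0592).

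Among the larger increases were genes listed at 0 in sham. Calr, an endoplasmic reticulum chaperone, was listed at 0 in the 3 wild-type sham libraries and at 43.5, 28.6 and 21.8 under imiquimod (adjusted p = 0.00284). The DNA ligase gene Lig1 (50.3, 14.7 and 31.7; adjusted p = 0.0145), the replicative helicase gene Mcm7 (28.3, 4.21 and 31.7; 0.0423), Nme1 (34.6, 14.7 and 5.94; 0.0358) and Hnrnpr (18.9, 6.32 and 19.8; 0.0485) were also listed at 0 in all wild-type sham libraries, so no fold is given. Birc5, the mitotic gene for survivin, was at 2.24, 0 and 0 in sham and 30.4, 33.7 and 41.6 in imiquimod (4.60 ± 1.33, adjusted p = 0.0310). Top2a, a topoisomerase of dividing cells, was at 0, 3.08 and 0 and then 15.2, 12.6 and 76.1 (4.01 ± 1.16, adjusted p = 0.0310). Lgals1, Rrs1 and Hdgf, each listed at 0 in 2 of 3 sham libraries, had log2 fold changes of 4.37, 4.27 and 3.95, each with an adjusted p of 0.0145. Such folds depend on the pseudocount. With 0.1 they were 6.59, 6.65 and 6.15 and not called (adjusted p = 0.105, 0.0589 and 0.0730), and with 10 they were 2.14, 1.77 and 1.84 and called. Birc5 and Top2a likewise had 6.94 and 6.28 with 0.1 (adjusted p = 0.139 and 0.114) and 2.07 and 1.74 with 10, where they were called. Arhgap45, Fam65b, Sp100, Kmt2a, Ptpn22 and Ms4a6b fell, with log2 fold changes from -4.12 (Arhgap45) to -3.10 (Ms4a6b) and adjusted p from 0.00338 (Sp100) to 0.0358 (Ptpn22), and so did Grap2 (-2.96 ± 0.77, adjusted p = 0.0131). Fam65b and Kmt2a were listed at 0 in 2 of 3 imiquimod libraries. Over the alternative settings their folds ran from -6.52 to -1.60 and from -6.12 to -1.57. Birc5, Lig1, Mcm7, Nme1, Hnrnpr, Top2a, Lgals1, Rrs1 and Hdgf are among the genes that lost their call without 1 library. For Birc5 and Top2a the highest value was reached without wild-type imiquimod replicate 3 (adjusted p = 0.0999 and 0.187).

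As groups, the lists of cell division and growth rose in wild-type cells. All 6 tested proliferation genes had positive fold changes, with a median of 3.58 on the log2 scale (camera adjusted p = 1.80e-05; adjusted p = 0.0794 with an estimated correlation). H2afz, Top2a and Birc5 were called over all genes, and 5 were called when adjusted over the list alone. H2afz, which encodes the histone variant H2A.Z, went from 10.59 ± 3.53 to 64.4 ± 19.5 (2.50 ± 0.65, adjusted p = 0.0136; 0.0687 without wild-type imiquimod replicate 3). All 9 DNA replication genes had positive fold changes (median 3.24, also without Lig1 and Mcm7; adjusted p = 1.80e-05; adjusted p = 0.0882 with an estimated correlation), with 2 called and 7 called when adjusted over the list alone. All 10 genes of mTORC1, Myc and ribosome biogenesis did so as well (median 1.71, adjusted p = 1.80e-05; adjusted p = 0.0794 with an estimated correlation). Of these Ncl and Npm1 were called, and 4 were called when adjusted over the list alone. The 8 genes of the unfolded protein response had a median of 1.53, or 1.48 without Calr (adjusted p = 0.000380; adjusted p = 0.0794 with an estimated correlation), with Calr called and 4 called when adjusted over the list alone. Beside these lists, plasma cell markers, which were not tested, summed to 0, 2.93 and 6.21 in wild-type sham and to 21.5, 15.8 and 6.93 in wild-type imiquimod libraries.

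Naive and memory regulators, type I interferon response, MHC class I and type 1 and cytotoxic genes fell as lists in wild-type cells, while the gamma delta T cell and T cell identity list did not pass. That list had 7 tested genes, 3 positive and 4 negative (median -0.72, adjusted p = 0.0722; adjusted p = 0.236 with an estimated correlation), with Lck called and 1 called when adjusted over the list alone. It leaves out Tcrd, the T cell receptor delta chain locus, which was called and fell from 70.4 to 21.5. Migration and homing genes did not pass either (11 tested, median -0.64, adjusted p = 0.0722; fry 0.0271). Of 16 naive and memory T cell regulators 15 had negative fold changes (median -1.79, adjusted p = 0.000162; adjusted p = 0.0794 with an estimated correlation). None was called, and 8 were when adjusted over the list alone. The 8 type I interferon response genes had a median of -2.03, or -1.97 without the 3 genes at 0 in a group (adjusted p = 0.00431; adjusted p = 0.0794 with an estimated correlation), with Ifi203 called and 3 called when adjusted over the list alone. The 9 MHC class I and antigen processing genes had a median of -0.84 (adjusted p = 0.0187; adjusted p = 0.0794 with an estimated correlation), with H2-K1 called and 3 called when adjusted over the list alone, but without wild-type imiquimod replicate 3 the adjusted p was 0.0842. All 5 type 1 and cytotoxic genes were negative (median -2.21, adjusted p = 0.0132; adjusted p = 0.0794 with an estimated correlation), with Cd27 called and 3 called when adjusted over the list alone.

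Immediate early and dissociation genes, which often mark handling stress, also fell in wild-type cells (12 tested, median -1.64, or -1.27 without Fos and Jund; adjusted p = 0.0144; adjusted p = 0.180 with an estimated correlation). Ier5 and Dusp2 were called and 3 were called when adjusted over the list alone, and without wild-type sham replicate 3 the list's adjusted p was 0.0543. The 7 cytokine receptors and SOCS genes (median -1.58, adjusted p = 0.0194; adjusted p = 0.160 with an estimated correlation) had no called member and 1 called when adjusted over the list alone. They were not called without wild-type sham replicate 2 (adjusted p = 0.0615) or wild-type imiquimod replicate 3 (0.0743). The 5 NF-kB feedback and target genes (median -1.21, adjusted p = 0.0318; adjusted p = 0.0882 with an estimated correlation) had no called member and 2 called when adjusted over the list alone. Their list was not called without wild-type sham replicate 2 (adjusted p = 0.0615) or wild-type imiquimod replicate 1 (0.0786), nor with no filter (0.320). In all 11 of 18 lists were called in wild-type cells, 12 by fry and 0 with an estimated correlation. With a mean of at least 20, where fewer lists keep 5 members, 2 were called. Cytosolic ribosomal proteins (39 tested, median 0.39, adjusted p = 0.0655) and oxidative phosphorylation genes (16 tested, median 0.95, adjusted p = 0.0801) did not pass.

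**Figure D2:**
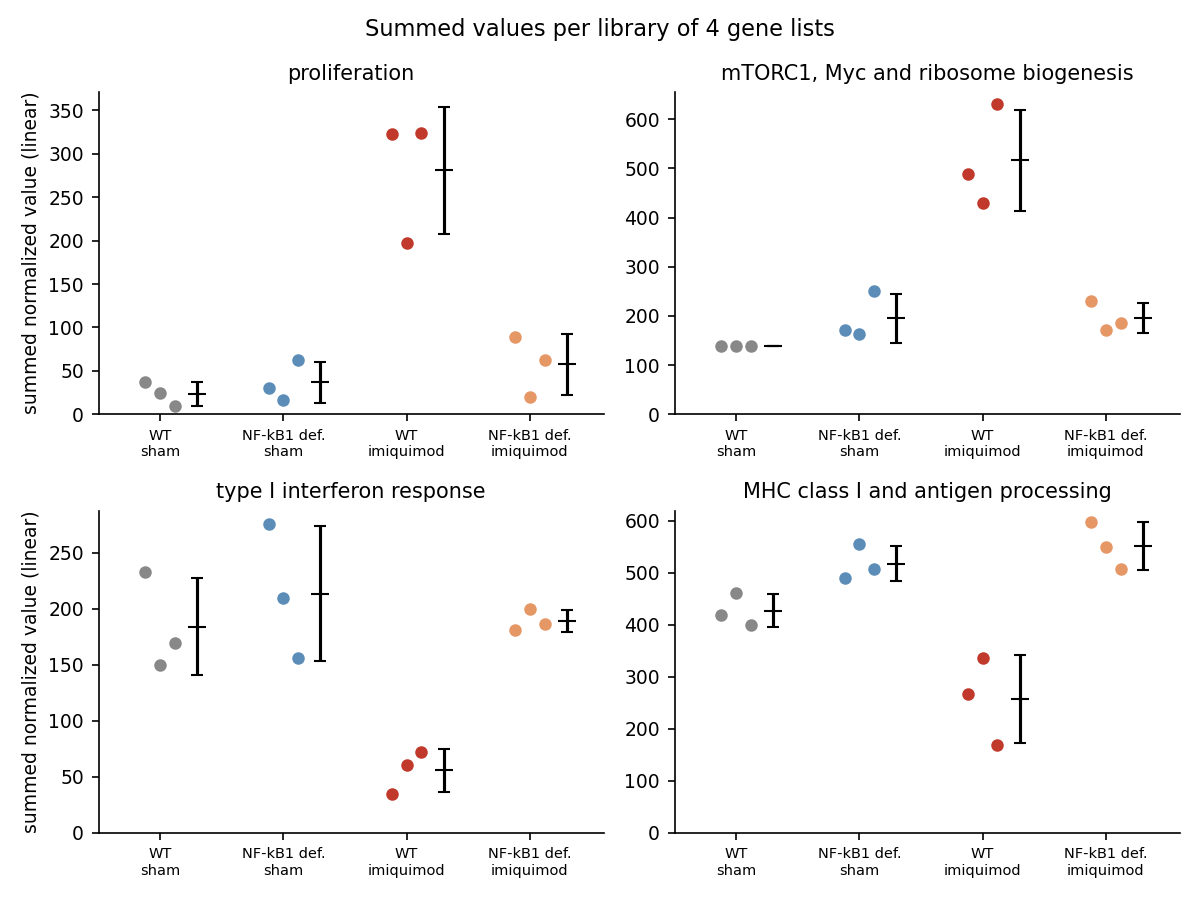
Summed normalized value per library of all members of 4 gene lists (proliferation; mTORC1, Myc and ribosome biogenesis; type I interferon response; MHC class I and antigen processing) in the 4 groups; points are libraries and bars with lines are mean ± SD of 3. Proliferation totals were 323, 197 and 324 in wild-type imiquimod libraries and between 9.32 and 89.4 in the other 9 libraries.

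The next comparison asked the same question in NF-kB1-deficient mice, and no gene was called. The gene with the lowest p was Pik3r1, a regulatory subunit of PI3 kinase, at 53.0 ± 10.3 in sham and 7.25 ± 4.05 in imiquimod (n = 3 each; log2 fold change -2.84 ± 0.78, limma adjusted p = 0.597). The actin-binding genes Cnn2 (2.78 ± 0.86) and Tagln2 (-1.76 ± 0.55) and D17H6S56E-5 (1.89 ± 0.59) each had an adjusted p of 0.650. Tuba1b was at 22.7 ± 2.0 and 29.2 ± 7.34 in NF-kB1-deficient sham and imiquimod libraries, Ncl at 73.3 ± 2.91 and 62.3 ± 9.53, and Malat1 at 1218 ± 41.9 and 892 ± 169 (-0.47 ± 0.18, adjusted p = 0.956). Npm1, not called either, did not overlap between these groups. It was at 19.1, 17.5 and 20.1 in sham and at 34.6, 40.2 and 41.2 in imiquimod. Limma called 0 genes, with 53 at an unadjusted p under 0.05, and 0 of 18 lists by camera, by fry or with an estimated correlation, with 3 lists at an unadjusted p under 0.05. The lowest list value was that of cytosolic ribosomal proteins (32 of 39 positive, median 0.38, adjusted p = 0.0973), which were called with a pseudocount of 10 (0.0160) and with a mean of at least 20 (0.0175). In a fit of these 6 libraries alone Pik3r1 was called (adjusted p = 0.00678). Groups did not overlap in 11.7% of genes, where chance gives at most 10% with an unknown spread, so this share decides nothing. A count of 0 at this depth does not show that nothing changed.

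For some lists the signs of the summaries differ in NF-kB1-deficient cells. MHC class I genes and type I interferon genes had medians of 0.12 and 0.11 but means of -0.23 and -0.37, and the test pointed down (adjusted p = 0.756 each). The proliferation list had a median of 0.44 (adjusted p = 0.756), with summed values of 30.5, 16.6 and 62.8 in sham and 89.4, 20.3 and 63.0 in imiquimod.

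The comparison of genotypes under sham cream asked what the loss of NF-kB1 changes without imiquimod. Again no gene was called. The lowest p belonged to Cnn2 (log2 fold change -3.0 ± 0.86), the kinase gene Taok1 (3.75 ± 1.16) and the splicing factor gene Rbm25 (-1.83 ± 0.55), each with a limma adjusted p of 0.757. Rbm25 (Entrez 67039; chromosome 12, 83631236 to 83683123) was at 56.0 ± 2.12 in wild-type and 15.3 ± 2.99 in NF-kB1-deficient sham libraries (n = 3 each). Taok1 was at 0, 3.90 and 1.24 in wild-type and at 33.8, 26.3 and 27.1 in NF-kB1-deficient sham libraries. Tuba1b was 9.59 ± 1.55 and 22.7 ± 2.0 (1.17 ± 0.53, adjusted p = 0.809). Limma called 0 genes, with 96 at an unadjusted p under 0.05, and 0 lists by camera, fry or with an estimated correlation, with 2 at an unadjusted p under 0.05. Those were MHC class I (median 0.49) and mTORC1, Myc and ribosome biogenesis (median 0.40), both with an adjusted p of 0.302. Groups did not overlap in 9.36% of genes, where chance gives at most 10% with an unknown spread, so this share decides nothing. Without NF-kB1-deficient sham replicate 1, Cnn2 was called (-4.23, adjusted p = 0.0286).

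Under imiquimod the comparison of genotypes asked what the loss of NF-kB1 changes in treated mice, and here the genotypes differed. Malat1 was higher in NF-kB1-deficient cells, at 892 ± 169 against 325 ± 83.0 in wild-type cells (mean ± SD, n = 3 each; log2 fold change 1.47 ± 0.18, limma adjusted p = 4.42e-11), a difference the naming rule takes for the interaction. MHC class I transcripts were higher: H2-K1 at 168 ± 13.2 against 55.4 ± 22.8 (1.66 ± 0.31, adjusted p = 0.000136), B2m, its light chain, at 182 ± 30.8 against 81.3 ± 18.4 (1.16 ± 0.29, adjusted p = 0.0152) and H2-Q7 at 50.2 ± 17.5 against 14.6 ± 7.80 (1.81 ± 0.53, adjusted p = 0.0486). Btg1 was at 42.9 ± 5.57 against 6.01 ± 1.33 (2.66 ± 0.60, adjusted p = 0.00510) and Cd27 at 38.9 ± 32.3 against 4.82 ± 1.30 (2.51 ± 0.66, adjusted p = 0.0249).

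The 8 genes lower in NF-kB1-deficient than in wild-type imiquimod libraries included Tuba1b and Ncl. Tuba1b was at 29.2 ± 7.34 against 139 ± 64.3 (-2.12 ± 0.53, adjusted p = 0.0152), and Ncl at 62.3 ± 9.53 against 164 ± 57.6 (-1.33 ± 0.36, adjusted p = 0.0290). Hsp90ab1, a cytosolic chaperone gene, was at 119 ± 29.7 against 285 ± 47.6 (-1.26 ± 0.31, adjusted p = 0.0124). Pabpn1 (-1.80, adjusted p = 0.00634), Rcc2 (-1.72, 0.0424) and Serbp1 (-1.48, 0.0252) were lower as well. Lck was at 26.8, 17.6 and 16.6 in NF-kB1-deficient and at 1.05, 0 and 6.93 in wild-type imiquimod libraries (3.04 ± 0.76, adjusted p = 0.0152). The antiapoptotic gene Bcl2 was at 27.9, 26.5 and 27.5 against 1.57, 5.26 and 0 (3.48 ± 0.92, adjusted p = 0.0252). Il7r (2.31), Dusp2 (2.02), Arl4c (2.53), Bcl9l (3.70), Sp100 (3.36), Utrn (3.11) and Ms4a6b (2.71) were also higher, with adjusted p from 0.0259 (Arl4c) to 0.0459 (Il7r). Folds of genes with listed zeros moved with the setting, from 1.62 to 4.83 for Bcl2 and from 1.48 to 5.95 for Bcl9l.

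In total 28 genes were called, 20 higher and 8 lower in NF-kB1-deficient cells, with 225 at an unadjusted p under 0.05. With equal totals the split was 27 and 5, and with a pseudocount of 10 it was 11 and 17. The groups did not overlap in 27 of the 28 and in 21.1% of all genes, where chance gives at most 10% with an unknown spread. This count moved with single libraries and settings. It was 4 without NF-kB1-deficient imiquimod replicate 2, 9 without replicate 3 of that group, 10 without its replicate 1 and 18 without NF-kB1-deficient sham replicate 1. It ran from 10 to 28 over 20 draws of reads thinned to equal depth. It was 18 with a pseudocount of 0.1, 17 in a fit of the 6 libraries alone, 3 with no filter and 0 without trend or robust, where 217 genes had an unadjusted p under 0.05. Malat1 and H2-K1 stayed called whichever library was left out, while 22 other genes followed through these settings lost their call without at least 1 library. Their highest adjusted p ran from 0.0537 (Btg1, without NF-kB1-deficient imiquimod replicate 3) to 0.409 (Cd27, without replicate 2 of that group). Without NF-kB1-deficient imiquimod replicate 2 the calls of B2m (adjusted p = 0.111), Hsp90ab1 (0.114) and Tuba1b (0.0591) also ended.

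The lists of interferon response and antigen presentation were higher in NF-kB1-deficient than in wild-type cells under imiquimod. All 9 MHC class I and antigen processing genes were positive (median 1.16, camera adjusted p = 0.000440, and 0.0304 with an estimated correlation), with H2-K1, B2m and H2-Q7 called over all genes and 3 called when adjusted over the list alone. All 8 type I interferon response genes were positive (median 2.0, or 1.70 without those at 0 in a group; adjusted p = 0.000440, and 0.0304 with an estimated correlation), with 1 called over all genes and 2 called when adjusted over the list alone. Type 1 and cytotoxic genes had a median of 2.04 (adjusted p = 0.00315; adjusted p = 0.0688 with an estimated correlation), with Cd27 called and 2 called when adjusted over the list alone. Naive and memory T cell regulators had a median of 1.36 with 14 of 16 positive (adjusted p = 0.00187; adjusted p = 0.112 with an estimated correlation), with Il7r called and 2 called when adjusted over the list alone. Cytokine receptors and SOCS genes had a median of 1.77 (adjusted p = 0.00377; adjusted p = 0.118 with an estimated correlation), with Il7r called and 3 called when adjusted over the list alone. Immediate early and dissociation genes had a median of 1.46, or 1.10 without those at 0 in a group (adjusted p = 0.00187; adjusted p = 0.121 with an estimated correlation), with Dusp2 called and 3 called when adjusted over the list alone.

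Division and growth lists were lower in NF-kB1-deficient cells under imiquimod. All 6 proliferation genes were negative (median -2.60, adjusted p = 0.000440; adjusted p = 0.112 with an estimated correlation), with none called and 4 called when adjusted over the list alone. All 9 DNA replication genes were negative (median -2.12, adjusted p = 0.000841; adjusted p = 0.158 with an estimated correlation), with none called and 0 called when adjusted over the list alone. Of 10 genes of mTORC1, Myc and ribosome biogenesis 9 were negative (median -1.03, adjusted p = 0.00205; adjusted p = 0.112 with an estimated correlation), with Ncl called and 2 called when adjusted over the list alone. In all 9 of 18 lists were called, 12 by fry and 2 with an estimated correlation. With a mean of at least 20, where fewer lists keep 5 members, none was called by camera, and with no filter 14 were. NF-kB feedback and target genes (median 1.70), oxidative phosphorylation (-0.67) and the unfolded protein response (-0.79) each had a camera adjusted p of 0.0508. By fry these lists had 0.0164, 0.171 and 0.144, and 1 NF-kB target was called when adjusted over the list alone. The 6 tested genes near Nfkb1 on chromosome 3 had a median of -0.41 (camera adjusted p = 0.128, fry 0.0346). H2afz is in this list and in the proliferation list, so the 2 lists are not separate evidence. Gamma delta T cell and T cell identity genes did not pass (median 0.47, 4 of 7 positive, camera adjusted p = 0.103), with Lck called and 2 called when adjusted over the list alone.

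The interaction asked whether the response to imiquimod differs between the genotypes. Malat1 fell in wild-type cells and its response differed by 1.49 ± 0.25 on the log2 scale in NF-kB1-deficient cells (limma adjusted p = 2.09e-05). Tuba1b and Ncl rose in wild-type cells, and their responses in NF-kB1-deficient cells were lower by test (-3.29 ± 0.75 and -2.21 ± 0.51, each with an adjusted p of 0.0110). Serbp1, an mRNA-binding protein gene (Entrez 66870; chromosome 6, 67238176 to 67297736), went from 45.6 ± 11.5 to 122 ± 59.1 in wild-type and from 91.7 ± 41.0 to 42.8 ± 20.7 in NF-kB1-deficient cells (mean ± SD, n = 3 each; -2.40 ± 0.56, adjusted p = 0.0110). Tagln2 (Entrez 21346; chromosome 1, 172500047 to 172507380) went from 18.8 ± 7.82 to 55.7 ± 28.5 and from 53.5 ± 21.4 to 14.4 ± 1.15 (-3.23 ± 0.78, adjusted p = 0.0137). Btg1 went from 47.9 ± 14.5 to 6.01 ± 1.33 and from 24.8 ± 8.02 to 42.9 ± 5.57 (3.59 ± 0.84, adjusted p = 0.0113). Rbm25 went from 56.0 ± 2.12 to 19.7 ± 12.7 and from 15.3 ± 2.99 to 43.0 ± 2.57 (3.12 ± 0.78, adjusted p = 0.0214).

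These 7 genes were the calls of the interaction, 3 positive and 4 negative, with 169 genes at an unadjusted p under 0.05. With equal totals the split was 6 and 4. The count was 2 without NF-kB1-deficient sham replicate 3, 2 without wild-type imiquimod replicate 3, 4 without NF-kB1-deficient imiquimod replicate 2 and 12 without wild-type imiquimod replicate 2. It ran from 3 to 7 over 20 draws of reads thinned to equal depth. It was 13 with a mean of at least 20, 1 with no filter (Malat1) and 0 without trend or robust, where 151 genes had an unadjusted p under 0.05. Malat1 stayed called whichever library was left out. Tuba1b was not called without wild-type imiquimod replicate 3 (adjusted p = 0.0712), and the highest adjusted p without 1 library was 0.0712 for Ncl, 0.0800 for Btg1, 0.0919 for Rbm25 and 0.130 for both Serbp1 and Tagln2. Rbm25 lost its call without any 1 of 9 libraries. Next in order of p, and not called, came Cd27 (3.35 ± 0.93, adjusted p = 0.0813), H2-K1 (1.55 ± 0.44, adjusted p = 0.0869) and Nucks1 (-3.13 ± 0.94, adjusted p = 0.138).

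Among lists, the response of DNA replication (median -1.90, camera adjusted p = 0.00121), of mTORC1, Myc and ribosome biogenesis (-1.73, 0.00121) and of proliferation genes (-2.60, 0.00128) was lower in NF-kB1-deficient cells. It was higher for cytokine receptors and SOCS genes (2.07, 0.00420), naive and memory regulators (1.21, 0.0118) and type 1 and cytotoxic genes (1.61, 0.0118). For these 6 lists the adjusted p was 0.165 with an estimated correlation. Ncl was the 1 called member. Adjusted over the list alone, the called lists had 2 in DNA replication, 1 in mTORC1, Myc and ribosome biogenesis, 1 in type 1 and cytotoxic genes and 1 in immediate early genes. The type I interferon response (1.59, or 2.17 without genes at 0 in a group; adjusted p = 0.0412; adjusted p = 0.165 with an estimated correlation), the immediate early genes (1.48, or 1.27; adjusted p = 0.0231; adjusted p = 0.218 with an estimated correlation) and the unfolded protein response (-1.12, or -0.75; adjusted p = 0.0373; adjusted p = 0.218 with an estimated correlation) were called too. Each of these 3 lost its call without single libraries: the interferon list without any of 7 libraries (adjusted p up to 0.103, without NF-kB1-deficient sham replicate 3), the immediate early list without any of 4 (up to 0.102, without NF-kB1-deficient sham replicate 2) and the unfolded protein response without any of 7 (up to 0.168, without wild-type sham replicate 2). The response of MHC class I and antigen processing genes did not differ by this test (median 0.54, 6 of 9 positive, camera adjusted p = 0.0829, and 0.165 with an estimated correlation), with 2 called when adjusted over the list alone. Nor did that of gamma delta T cell and T cell identity genes (median 1.10, 5 of 7 positive, camera adjusted p = 0.0584), also with 2. NF-kB feedback and target genes, with 5 of 5 positive (median 1.23), had a camera adjusted p of 0.0587 and a fry adjusted p of 0.0488. In all 9 lists were called, 6 by fry, 0 with an estimated correlation, and 0 with a mean of at least 20, where fewer lists keep 5 members.

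The wild-type response genes were then followed across the other comparisons. They were chosen on wild-type libraries, so their wild-type folds lean high. For the same reason their genotype folds under sham lean in the direction of the wild-type response, and those under imiquimod lean against it. The 26 genes higher in the wild-type response had a median log2 fold change of 3.38 there and 0.33 in NF-kB1-deficient cells, where 18 had the same direction and none was called. The 25 lower genes had a median of -2.83 in wild-type and 0.01 in NF-kB1-deficient cells, with 12 in the same direction. Under sham the 26 genes had a genotype median of 0.77 (23 positive) and the 25 genes one of -0.52 (19 negative), with none called. Both medians lie on the side to which the choice of genes leans, so they show no genotype shift by themselves. No gene was called in both responses. Across the tested genes, which are not independent replicates, the responses had a correlation of 0.0979, and 52.8% of genes had the same sign.

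**Figure D3:**
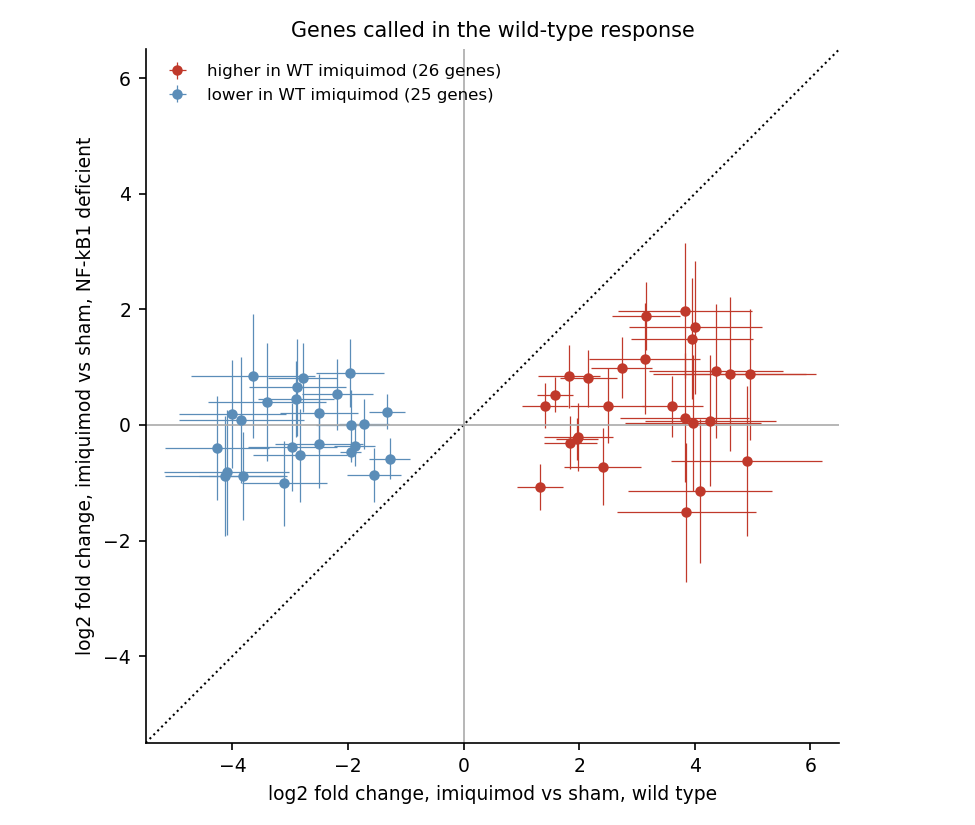
Log2 fold change of imiquimod against sham in wild-type cells (x axis) and in NF-kB1-deficient cells (y axis) for the 51 genes called in wild-type cells; lines are SE and the dotted line marks equal responses. The 26 higher genes (red) have a median of 3.38 on the x axis and 0.33 on the y axis, and the 25 lower genes (blue) -2.83 and 0.01.

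A score per library, the mean log2 value of the higher minus that of the lower genes, was -3.02 ± 0.47 in wild-type sham, -1.45 ± 0.63 in NF-kB1-deficient sham, 2.92 ± 0.57 in wild-type imiquimod and -0.998 ± 0.642 in NF-kB1-deficient imiquimod libraries (mean ± SD, n = 3 each). In NF-kB1-deficient cells imiquimod and sham differed by 0.45 (two-sided exact permutation p = 0.5). The smallest p that 3 against 3 libraries allow is 0.1. Scores of wild-type libraries were not tested against others, because the genes were chosen on them.

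The wild-type response and the genotype difference under imiquimod share the 3 wild-type imiquimod libraries, so their values are tied by construction. Of genes higher in the wild-type response 4 were lower in NF-kB1-deficient imiquimod libraries, and of those lower in the response 12 were higher. Simulated unchanged groups gave 0 in each direction over 100 simulations, but they called at most 1 gene in either comparison, so that this 0 is fixed by the small number of calls. Independent lists of these sizes would share 0.132 and 0.318 genes, which leaves out the shared libraries. Neither value shows an excess of the overlap. The correlation across genes was -0.774 against -0.501 in simulation, and the covariance -1.60 against -0.588. The 3 shared libraries are too few to split, and part of the overlap may come from them. The genotype differences under sham and under imiquimod had a correlation across genes of -0.0291, with the same sign in 50.03% of genes and no gene called in both.

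Single cytokine genes and the receptor genes for IL-1 and IL-23 had few values above 0, in a table where Gapdh is also listed at 0 in 5 libraries. Il17a, Il22 and the IL-1 receptor gene Il1r1 were listed at 0 in all 12 libraries. Il17f was at 0, 6.32 and 33.7 in wild-type imiquimod and at 5.51, 0 and 5.51 in NF-kB1-deficient imiquimod libraries, and listed at 0 in sham. Ifng was above 0 only in wild-type imiquimod replicate 3 (15.8) and the IL-23 receptor gene Il23r only in wild-type imiquimod replicate 2 (6.84). Mki67, a proliferation marker, was at 11.2, 5.79 and 0 in wild-type imiquimod and at 1.25, 2.44 and 5.51 in NF-kB1-deficient imiquimod libraries. These genes, with Tbx21, stayed under the filter and were not tested.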

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

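The test of other cell types, the genes Tcrd, Tcrb, Tcrg, Tcrg-C2, Thy1 and Ptprc and the settings with equal totals, with a common floor and with thinned reads were chosen after the result they bear on was seen. The results here stand out because the response to imiquimod differed between the genotypes by a test of that difference.

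For 7 genes the interaction was called, as the response in NF-kB1-deficient minus that in wild-type cells on the log2 scale with its limma adjusted p. These were Malat1 at 1.49 (2.09e-05), Btg1 at 3.59 (0.0113), Rbm25 at 3.12 (0.0214), Tuba1b at -3.29 (0.0110), Tagln2 at -3.23 (0.0137), Serbp1 at -2.40 (0.0110) and Ncl at -2.21 (0.0110). Left-out libraries ended calls as follows. Without wild-type imiquimod replicate 3 those of Tuba1b (0.0712), Ncl (0.0712), Serbp1 (0.0712), Tagln2 (0.0744) and Rbm25 (0.0712) ended. Without NF-kB1-deficient sham replicate 3 those of Ncl (0.0547), Serbp1 (0.130), Tagln2 (0.130), Btg1 (0.0599) and Rbm25 (0.0599) ended, and without NF-kB1-deficient imiquimod replicate 2 those of Ncl (0.0522), Serbp1 (0.0623) and Rbm25 (0.0878). Btg1 and Rbm25 also lost theirs without wild-type sham replicate 1 (0.0798 and 0.0646) and without NF-kB1-deficient imiquimod replicates 1 (0.0673 each) and 3 (0.0800 and 0.0869), Tagln2 and Rbm25 without wild-type sham replicate 3 (0.0610 each), and Rbm25 without wild-type sham replicate 2 (0.0919) and NF-kB1-deficient sham replicate 1 (0.0510). Of 100 drawn reassignments of genotype within treatment, the real one included, 2 called as many genes as the real 7, and the highest other count was also 7. Such reassignments also break up the genotype difference under imiquimod. They therefore test any effect of genotype, and cannot show that the interaction calls exceed chance. Without trend or robust limma called 0 genes, with 151 at an unadjusted p under 0.05.

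For 9 lists the interaction was called, with these median log2 differences: cytokine receptors and SOCS 2.07, immediate early and dissociation genes 1.48, naive and memory T cell regulators 1.21, type 1 and cytotoxic genes 1.61, type I interferon response 1.59, DNA replication -1.90, mTORC1, Myc and ribosome biogenesis -1.73, proliferation -2.60 and the unfolded protein response -1.12. None was called with an estimated correlation, where the adjusted p was 0.165 or 0.218.

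The pattern behind these results is a wild-type response of 51 genes beside a response in NF-kB1-deficient cells in which limma called none (53 genes at an unadjusted p under 0.05). Uneven detection floors were argued against for the wild-type calls, since 45 of the 51 genes stayed called once all values under 1.98 were set to 0. That floor changed only 883 of the 16276 values above 0 in tested genes. Uneven numbers of implied reads as the whole cause of those calls were argued against too. Here 40 stayed called in the median of 20 draws (34 to 44) that thinned the implied reads to those of the shallowest library. The draws treat reads as independent. If reads are copies of few molecules, they do not even out the molecules per library, and cannot speak to that. A shift from a few abundant transcripts was also argued against, since 43 stayed called at equal totals without the 10 most abundant genes. These checks bear on the wild-type calls, and cannot say why 0 genes were called in NF-kB1-deficient cells. Other cells in the wild-type imiquimod libraries, which the Vg4 and Vd4 gate should remove, cannot be told apart from a change within the sorted cells: the highest share of any other-cell list was 0.0918% of the summed values, but 6 of 8 such lists had no tested member, and Tcrd fell from 70.4 to 21.5 (adjusted p = 0.00905, but 0.0505 without wild-type sham replicate 3 and 0.0574 without wild-type imiquimod replicate 1) while Tcrb was at 88.1 and 68.8, Tcrg-C2 at 18.6 and 17.8 and Thy1 at 26.0 and 36.6, and Tcrg at 45.3 and 24.4 and Ptprc at 49.9 and 16.3, without passing the test. It also stays open that the libraries labelled NF-kB1 deficient and imiquimod came from mice that were not treated. They differed from sham in 0 genes and lists, and the simulated test found 41.3% of 4-fold changes, so this cannot be told apart from a weak response. Single settings called Pik3r1 (limma adjusted p = 0.00678 in a fit of the 6 libraries) and ribosomal proteins (camera adjusted p = 0.0160 with a pseudocount of 10, 0.0175 with a mean of at least 20). Pik3r1 went from 53.0 to 7.25 in NF-kB1-deficient and from 30.1 to 5.56 in wild-type libraries. D17H6S56E-5 went from 14.2 to 51.1 (limma adjusted p = 0.650) and, called in wild-type cells, from 8.81 to 80.0. Cnn2 and Tagln2, also among the lowest p in NF-kB1-deficient cells, moved the other way in wild-type cells (30.9 to 24.8 and 18.8 to 55.7). A loss of the response without NF-kB1 is the biological hypothesis that the design names, and these tests leave it possible but not shown.

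Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For the wild-type response the real split called 51 genes and the highest other 1, so that 1 of 10 splits reached the real count. For the genotypes under imiquimod the real split called 28 and the highest other 0, again 1 of 10. For the response of NF-kB1-deficient cells (real 0, highest other 0) and the genotypes under sham (real 0 by limma with 96 at an unadjusted p under 0.05, highest other 1), a count of 0 is reached by any split (10 of 10), so these splits show nothing about chance.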

How the results depend on the processing

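Equal totals, median-of-ratios factors, a common floor, library weights, the deposited log2 values and reads thinned to equal depth were tried only after the data were seen; the other settings were planned. Other size factors, other count tests and voom were planned for counts and were not run, because the table holds log2 normalized values. Of the values recomputed, 2297 kept their side of the threshold or stayed close, 464 kept their direction and lost their call, 86 moved further and 9 changed sign. All 9 were folds of Nfkb1, which was called in no setting. All 51, 28 and 7 called genes kept their direction in every setting in which they were tested. Where a call was lost the cause was not tested, except that no filter adds many genes near 0 to the adjustment, a mean of at least 20 leaves fewer genes and lists, and a fit of 6 libraries has fewer degrees of freedom. Depth limits all of this: with 20507 to 69454 implied reads per library, most genes carry few reads.

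Genes called in the wild-type response (51) fell to 26 with a pseudocount of 0.1, 11 with no filter, 18 without trend or robust (14 of the 51 among them) and 28 in the fit of 6 libraries, and ran from 26 (without wild-type sham replicate 3) to 73 (without wild-type imiquimod replicate 2) when 1 library was left out. The genotype count under imiquimod (28) became 18, 3 (Malat1, H2-K1 and Ms4a4b), 0 (217 at an unadjusted p under 0.05) and 17 in those settings and ran from 4 (without NF-kB1-deficient imiquimod replicate 2: Malat1, H2-K1, Ms4a4b and Btg1) to 42 (without wild-type imiquimod replicate 2). The interaction count (7) became 1 with no filter, 13 with a mean of at least 20 and 0 without trend or robust (151 at an unadjusted p under 0.05), and ran from 2 (without NF-kB1-deficient sham replicate 3 or wild-type imiquimod replicate 3) to 12 (without wild-type imiquimod replicate 2). In NF-kB1-deficient cells 1 gene (Pik3r1) was called in the fit of 6 libraries, and under sham the range was 0 to 1 (Cnn2, without NF-kB1-deficient sham replicate 1). Over 20 draws of reads thinned to equal depth the counts ran from 37 to 53, 10 to 28 and 3 to 7 for the wild-type response, the genotypes under imiquimod and the interaction, and were 0 in NF-kB1-deficient cells by limma (58 genes at an unadjusted p under 0.05 in the first draw). Ms4a4b was chosen after its values were seen. The Nfkb1 fold under imiquimod (0.29) ran from -0.96 (without wild-type imiquimod replicate 3) to 0.57 with 1 library left out, and was -0.14 with a pseudocount of 10, -0.12 with library weights and -0.37 with thinned reads. Under sham (-0.12) it ran from -0.74 to 0.38, with a positive sign without wild-type sham replicate 1 or 2 or NF-kB1-deficient sham replicate 2 or 3, and was 0.025 with library weights.

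Equal totals moved the median fold of all genes by -0.14 in the wild-type response, 0.20 between genotypes under imiquimod and 0.17 in the interaction, so genes with smaller changes sit differently against the rest; the other shifts stayed under 0.1.

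Lists called with an estimated correlation were 0 in the wild-type response, 2 between genotypes under imiquimod and 0 in the interaction, and with a mean of at least 20 they were 2, 0 and 0. With no filter 14 were called between genotypes under imiquimod. In NF-kB1-deficient cells 1 list was called with a pseudocount of 10 and 1 with a mean of at least 20 (ribosomal proteins, adjusted p = 0.0160 and 0.0175), and 1 with no filter (erythroid and platelet genes, 0.0323). With an estimated correlation the adjusted p in the wild-type response was 0.0794 for proliferation, mTORC1, unfolded protein response, naive and memory, type 1, interferon and MHC class I lists, 0.0882 for DNA replication and NF-kB targets, 0.160 for cytokine receptors and 0.180 for immediate early genes. Between genotypes under imiquimod it was 0.0688 for type 1 genes, 0.112 for proliferation, mTORC1 and naive and memory lists, 0.118 for cytokine receptors, 0.121 for immediate early genes and 0.158 for DNA replication. In the interaction it was 0.218 for immediate early and unfolded protein response genes and 0.165 for the other 7. By fry the lost calls were immediate early genes in wild-type cells (0.0540) and, in the interaction, DNA replication (0.0786), immediate early (0.0967), naive and memory (0.0501) and unfolded protein response genes (0.153). With a mean of at least 20, immediate early and naive and memory genes had 0.0674 each between genotypes and 0.136 and 0.203 in the interaction. With no filter NF-kB targets had 0.320 in wild-type cells, and interferon and unfolded protein response genes 0.178 and 0.336 in the interaction.

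With 1 library left out, adjusted p ran over 0.05 for these lists. In wild-type cells the ranges were 0.00894 to 0.0743 for cytokine receptors (0.0615 without wild-type sham replicate 2, 0.0743 without wild-type imiquimod replicate 3), 0.00265 to 0.0543 for immediate early genes (highest without wild-type sham replicate 3), 0.00966 to 0.0842 for MHC class I (highest without wild-type imiquimod replicate 3) and 0.0110 to 0.0786 for NF-kB targets (0.0615 without wild-type sham replicate 2, 0.0786 without wild-type imiquimod replicate 1). In the interaction they were 0.00392 to 0.102 for immediate early genes (0.0639 without wild-type sham replicate 3, 0.102 without NF-kB1-deficient sham replicate 2, 0.0520 without wild-type imiquimod replicate 2 and 0.0525 without NF-kB1-deficient imiquimod replicate 3) and 0.0166 to 0.103 for the interferon response. The latter was over 0.05 without wild-type sham replicates 1 (0.0663) and 2 (0.0535), NF-kB1-deficient sham replicate 3 (0.103), wild-type imiquimod replicates 1 (0.0699) and 2 (0.0667) and NF-kB1-deficient imiquimod replicates 2 (0.0559) and 3 (0.0525). The unfolded protein response ran from 0.00341 to 0.168, and was over 0.05 without wild-type sham replicates 1 (0.0757) and 2 (0.168), NF-kB1-deficient sham replicates 1 (0.0608) and 3 (0.102), wild-type imiquimod replicate 3 (0.114) and NF-kB1-deficient imiquimod replicates 1 (0.0668) and 2 (0.0544).

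No strong pairing by replicate number was seen, but a weak one is not excluded. Deviations of same-numbered libraries from their group means correlated at -0.00983 to 0.0609 over 18 pairs (median 0.0164), with none above 0.1. The 36 pairs with other numbers ran from -0.0638 to 0.0372 (median -0.00386), a little lower. With the replicate number as a block 55, 0, 0, 32 and 7 genes were called in the order of the comparisons, with 51 of 51, 28 of 28 and 7 of 7 calls kept.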

Other observations

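The test of few starting molecules, the numbers of genes at each number of reads, the non-overlap counts and the list medians without genes at 0 in a group were chosen after the values were seen. So were the genes Tcrd, Tcrb, Tcrg, Tcrg-C2, Thy1, Cd44 and Icos. Tcrd, the T cell receptor delta chain locus, was among the transcripts that fell in wild-type cells under imiquimod, from 70.4 ± 5.74 to 21.5 ± 8.32 (mean ± SD, n = 3 each; log2 fold change -1.73 ± 0.43, limma adjusted p = 0.00905). It was at 59.7 ± 17.2 and 58.4 ± 4.65 in NF-kB1-deficient sham and imiquimod libraries. Tcrd lost its call without wild-type sham replicate 3 (adjusted p = 0.0505) and without wild-type imiquimod replicate 1 (0.0574). Reads on Tcrb, the beta chain locus, were at 88.1 ± 14.9 and 68.8 ± 12.5 in wild-type sham and imiquimod libraries (-0.35, adjusted p = 0.606). In the same libraries Tcrg, the gamma chain locus, was at 45.3 ± 16.6 and 24.4 ± 18.5 (-1.05, adjusted p = 0.193), Tcrg-C2 at 18.6 ± 8.98 and 17.8 ± 5.05 (0.01, adjusted p = 0.997) and Thy1 at 26.0 ± 8.94 and 36.6 ± 11.1 (0.50, adjusted p = 0.591). Cd44 and Icos, genes of T cell activation, did not pass the test. Cd44 was at 1.12, 8.05 and 0 in sham and at 19.1, 22.1 and 53.5 in imiquimod (adjusted p = 0.0706), and Icos at 0, 9.19 and 0 and then 17.8, 22.1 and 21.8 (adjusted p = 0.0835). The activation and checkpoint list that holds such genes, with 4 tested members, overlapped between the groups: it summed to 21.8, 54.6 and 30.4 in wild-type sham, 37.9, 87.6 and 65.1 in NF-kB1-deficient sham, 49.0, 61.7 and 107 in wild-type imiquimod and 66.4, 49.6 and 54.4 in NF-kB1-deficient imiquimod libraries, without a test.

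Other lists with too few tested members are given as summed normalized values per library, without a test. Glycolysis and hypoxia genes summed to 55.9, 63.4 and 42.9 in wild-type sham, 40.1, 59.7 and 39.0 in NF-kB1-deficient sham, 95.4, 138 and 121 in wild-type imiquimod and 62.8, 43.4 and 55.0 in NF-kB1-deficient imiquimod libraries. The IL-17 program of gamma delta T cells summed to 45.8, 103 and 143, then 80.4, 52.0 and 71.1, then 108, 122 and 47.5, then 85.4, 75.1 and 72.7 in the same order of groups. Again in that order, cytokine and growth factor genes summed to 7.83, 10.3 and 1.24, then 23.5, 2.17 and 11.3, then 0, 23.2 and 59.2, then 16.3, 10.5 and 11.4, so that the groups overlap. Genes of IL-1 and IL-23 receptor signalling summed to 88.3, 92.4 and 43.1, then 90.8, 88.7 and 51.0, then 41.9, 82.1 and 23.8, then 57.8, 45.4 and 62.2. The NF-kB subunits summed to 7.83, 11.9 and 26.1, then 21.3, 1.10 and 11.3, then 19.9, 21.0 and 23.8, then 5.41, 14.7 and 11.7. Genes of lipid uptake and synthesis summed to 18.5, 33.7 and 38.0, then 34.2, 4.38 and 73.6, then 13.1, 12.1 and 55.5, then 52.0, 22.8 and 38.2. Transcripts encoded by the mitochondrial genome were listed at 0 in all 12 libraries, so they give no measure of RNA quality.

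Markers of other cells were low in the lists fixed beforehand, which leave out Tcrb. The erythroid and platelet list took 0.153% and the B cell list 0.0577% of the summed values in NF-kB1-deficient imiquimod replicate 3, where the other libraries stayed lower for both lists. The macrophage, monocyte and dendritic cell list took 0.159% in NF-kB1-deficient sham replicate 1, its highest share, and 0.0918% in wild-type imiquimod replicate 2. Plasma cell genes took 0%, 0.00864% and 0.0179% in the wild-type sham libraries, 0.0583%, 0.0421% and 0.0171% in the wild-type imiquimod libraries and 0.0772% in NF-kB1-deficient imiquimod replicate 3.

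Many genes were listed at 0 in one replicate and stood well above 0 in another of the same group. This held, with a library at 0 and another at 10 or more, for 1057 of 6235 combinations of gene and group (17.0%), where Poisson sampling of the implied reads would give 5.62 (0.0901%), a ratio of 188. A candidate explanation is that each library was made from few RNA molecules that were then copied, so that reads are not independent. Differences between the mice or samples would raise the same ratio, and without molecular identifiers the ratio alone cannot tell the 2 apart. Within some single libraries the number of genes at 1 to 6 reads fell and then rose. It was 438, 221, 197, 240, 253 and 196 in wild-type sham replicate 1. In NF-kB1-deficient sham replicate 2 it was 315, 146, 147, 187, 217 and 175. In wild-type sham replicate 2 and NF-kB1-deficient imiquimod replicate 1 it only fell from 3 to 6 reads. Differences between samples cannot give such a rise, and copied molecules could, but this was not tested. An example of a 0 beside high values was Bcl9l, at 23.5, 31.2 and 0 in wild-type sham libraries. The housekeeping gene Gapdh, with low values, did not reach this mark within a group. It was at 4.47, 3.42 and 0 in wild-type sham and at 4.19, 5.26 and 15.8 in wild-type imiquimod libraries.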
